A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

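Two-colour arrays of yeast open reading frames were used, each hybridised with RNA of the strain with CadA and RNA of the strain with the D398A mutant. Per the labels, total RNA was copied to cDNA and labelled indirectly through aminoallyl-dUTP, and dyes were swapped on arrays 2 and 4. The deposited values are 1 normalized log ratio per probe and array in a table of the whole series. Per the submitters' processing notes they were made with limma 3.2.1. The normalization, the background correction and the handling of spots are not given in the sources used here, and scanner values were not used here. The deposited values were taken as log2 ratios because limma works on that scale; the base is not stated, and a fold given in the text assumes base 2. All 4 columns matched 1 sample each by name, and 0 columns were left unused.

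Array medians were -0.04, -0.09, 0.01 and 0.02 on arrays 1 to 4, so each array was already centred near 0. The SDs of all probes were 0.87, 0.95, 0.46 and 0.47. Between 10.8% and 38.5% of an array's variance lay between the 48 print blocks that the probe identifiers name. The same 54 probes were missing on every array.

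Probe names came from the platform annotation, with symbols updated through gene identifiers to the R64 table of annotated genes. Of 6216 probes, 3344 had 1 gene symbol, 387 had several and 2485 had none here. Of the 3344, 3343 matched the R64 table. A probe with several symbols or none was kept as a feature without a name. Probes of a gene were averaged, which gave 5946 features, 3099 of them named genes. The turned means of the first 2 probes differed in sign for 71 of the 206 genes with more than 1 probe. The build behind the probes is not given in the sources used here, so no coordinates are printed. Gene length is that of the R64 table and was known for 3098 genes.

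The direction of the ratio could not be taken from the table. The design fixed before the data were examined turned the sign on arrays with CadA in Cy3, unless arrays of opposite dye orientation correlated above 0, which was to be read as already turned. All 4 such pairs did correlate above 0 across probes (Pearson r between 0.009 and 0.35, mean 0.16), against 0.18 and -0.02 for the pairs of 1 orientation. After block centring the opposite pairs ran from -0.011, for arrays 3 and 4, to 0.37 (mean 0.20). The pairs of 1 orientation then stood at 0.34 and 0.23, so the order of the 2 kinds of pair depends on this step. Followed word for word on the values as deposited, that rule leaves the signs as deposited. A check chosen after this was seen differed between the readings. The means of 2 probes of 1 gene correlated at r = 0.34 over 206 genes in turned signs (rho 0.41, permutation p = 2e-05, adjusted p = 8e-05 over 4 such tests). In deposited signs r was -0.04 (rho -0.05, permutation p = 0.55, adjusted p = 0.55). The difference of 0.38 had a 95% bootstrap interval of 0.19 to 0.59. After block centring the turned r was 0.25, and on single arrays r ran from 0.03 on array 1 to 0.54 on array 4. In a table already turned, the turned mean would hold each gene's dye effect, which 2 probes may share as well. The check therefore does not settle the reading. KAR2 and 4 other ER genes changed sign with the dye orientation, which was seen first and is no independent reason. Both readings are reported, with the turned signs leading. The turned sign is + on arrays with CadA in Cy3 and - on the others. In limma's usual convention the numerator is Cy5, but no source used here states it, so no strain is named for either side.

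Each feature's mean over the 4 arrays was tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A feature needed values on at least 3 arrays. A fit with a strain and a dye coefficient tested the dye effect. An exact sign test over 4 arrays cannot go below p = 0.125, and limma's test draws on the spread of all features.

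Gene lists were fixed from general knowledge before the data were examined. Of 27 lists, 26 had at least 4 measured genes and were tested with limma's camera (preset correlation 0.01), two-sided and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. Of 6 lists called in turned signs and 1 in deposited signs by the preset correlation, 0 held with an estimated correlation. In turned signs the estimate lay below the preset for ER chaperones (-0.10) and ER to Golgi traffic (-0.04). Genes varying together therefore do not account for the loss of these calls. Camera with a preset correlation takes its degrees of freedom from the number of features. With an estimated correlation it takes them from the 4 arrays. The preset p-values therefore treat genes, and not arrays, as replicates. Among 1000 random lists of 9 named genes, 4.3% had a camera p below 0.05 in turned signs, and among 1000 of 49 genes 1.9%. Random lists were not chosen to hold genes that vary together, as lists of related genes may.

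Genes are named by a rule fixed before the data were examined: the 10 highest and the 10 lowest past the threshold with the same sign on every array, or, where none pass, the 5 most extreme with the same sign on all 4 arrays. The rule adds up to 3 genes of each list with the largest absolute mean, and 13 genes named in every case, of which 5 were measured as named genes (KAR2, GSH1, MET17, ZRT1 and HSP12). In deposited signs the text names the first group and the list genes of the called list. The text gives all other ER chaperone genes, MPD2, SIL1, EPS1, CNE1 and CPR5, because their list had the lowest p, a choice made after their values were seen.

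The fits were tested on simulated data with the real spread of 5946 features, 200 of them changed. A log2 change of 1 was recovered for 0% of them, a change of 2 for 71.5% and a change of 3 for 92%. Camera called a shift of 0.5 in 9 genes in 17 of 20 runs, with 0.1 other lists called per run. Noise was drawn independently for each gene, without print-block effects. The low number of other lists called therefore need not hold for real genes that vary together.

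Alternatives fixed beforehand were the dye term, averaging of arrays in opposite-dye pairs, median centring, scaling to 1 spread, the minimum of arrays, the median over probes or probes tested 1 by 1, robust or no shrinkage, a 1.5-fold minimum, a threshold of 0.01, leaving out each array, each dye orientation alone, other list tests, shared list members left out, and all signs turned. Added after the data were examined were block centring with and without the dye term, array weights, removal of the length trend, and arrays 1 and 2 or 3 and 4 alone. The signs as deposited follow from the rule fixed beforehand, and it was the lead of the turned signs that was chosen after the data were examined. Figures were drawn with matplotlib 3.10.9.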

Results

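Expression was compared between 2 transformants of the budding yeast strain W303-1A, each exposed to 1 µM cadmium for 1 h at 30 °C after growth to an OD600 of 0.4 in minimal medium. The first made CadA, a metal-transporting P-type ATPase of the bacterium Listeria monocytogenes. The second made its D398A mutant, in which alanine replaces an aspartate. RNA of both strains was hybridised together on each of 4 two-colour arrays of yeast open reading frames. CadA RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4, so each dye orientation was covered by 2 arrays. Of 6216 probes, 6162 had a value on every array and 54 had none on any. The number of arrays limits the precision. The labels do not say whether the arrays came from separate cultures, so p-values of single genes measure a spread between arrays that may be technical. List p-values from camera with its preset correlation rest on the number of genes and do not measure that spread.

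The comparison asks which genes differ between cells with the working transporter and cells with the mutant under the same cadmium dose. The deposited table does not state which dye is the numerator of its log ratio. Values below were therefore turned by the dye labels to run 1 way on all arrays, and positive values are those on the side of KAR2. Which strain that side stands for is not settled: it is CadA if the numerator is Cy3 and D398A if it is Cy5. The values in the signs as deposited are given as a separate reading further on. The choice of the turned signs as the leading reading was made after the data were examined and is not settled by them. If the table was already turned to 1 strain direction, the turned values hold dye effects and not strain differences.

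Genes for protein folding in the endoplasmic reticulum (ER) lay together on 1 side of the comparison. The list of ER chaperones and disulphide-forming enzymes holds 18 genes, of which 9 were measured. HAC1, IRE1, PDI1 and ERO1, among the genes to be named in every case, had no measured value under their names. Of the 9 measured genes of the list, 8 had a positive mean and 5 were positive on all 4 arrays. KAR2, the main ER chaperone of the Hsp70 family, had a log2 ratio of 1.04 ± 0.84 (SD, n = 4), or 2.06-fold. FPR2, a prolyl isomerase of the ER, reached 1.70 ± 1.33, and MPD1, a relative of protein disulphide isomerase, reached 1.45 ± 0.75. Both were positive on all 4 arrays. KAR2 read 2.23 on array 4 and averaged 0.64 without it, and FPR2 read 3.66 on array 2 and averaged 1.04 without it. LHS1, another ER chaperone, averaged 1.47 ± 1.40 and was positive on 3 arrays. SIL1, the exchange factor of Kar2, averaged 0.54 ± 0.26 and MPD2 0.30 ± 0.25, each positive on all 4 arrays. EPS1 at 0.07 ± 0.86, the lectin gene CNE1 at 0.00 ± 0.59 and CPR5 at -0.16 ± 0.21 lay near 0.

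The median of the 9 ER genes was 0.54, and the list medians of the 4 arrays averaged 0.58 ± 0.24 (SD), with a positive value on each. The list was shifted in limma's camera test with its preset correlation (adjusted p = 3.7e-06 over 26 lists). With an estimated correlation between genes the adjusted p was 0.31 and the raw p 0.012. The estimate was -0.10, below the preset 0.01, so genes of the list varying together did not raise the p. Degrees of freedom came from the 4 arrays with the estimate and from the number of features with the preset. No ER gene passed the adjustment over all 5946 features in the fit of 4 arrays, and 4 did when adjusted over the list alone: MPD1 at 0.016, FPR2 at 0.020, and KAR2 and LHS1 at 0.034 (limma). Without array 2 the number was 3, without array 3 it was 2 (FPR2 and MPD1), and without array 4 it was 0 (smallest adjusted p = 0.070). Over all features FPR2 passed when arrays 1 with 4 and 3 with 2 were averaged first (adjusted p = 0.035). KAR2 (0.015) and LHS1 (0.0040) passed on arrays 3 and 4 alone, a split chosen after the data were seen. The fits of averaged pairs and of these 2 arrays use 2 values per gene, so their p-values lean on the spread of all features. The list's camera call held in each of the 4 fits without 1 array, with medians between 0.46 and 0.64. It was lost on the 2 arrays with CadA in Cy5 alone, where the median was 0.56 and the adjusted p 0.13.

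**Figure D1:**
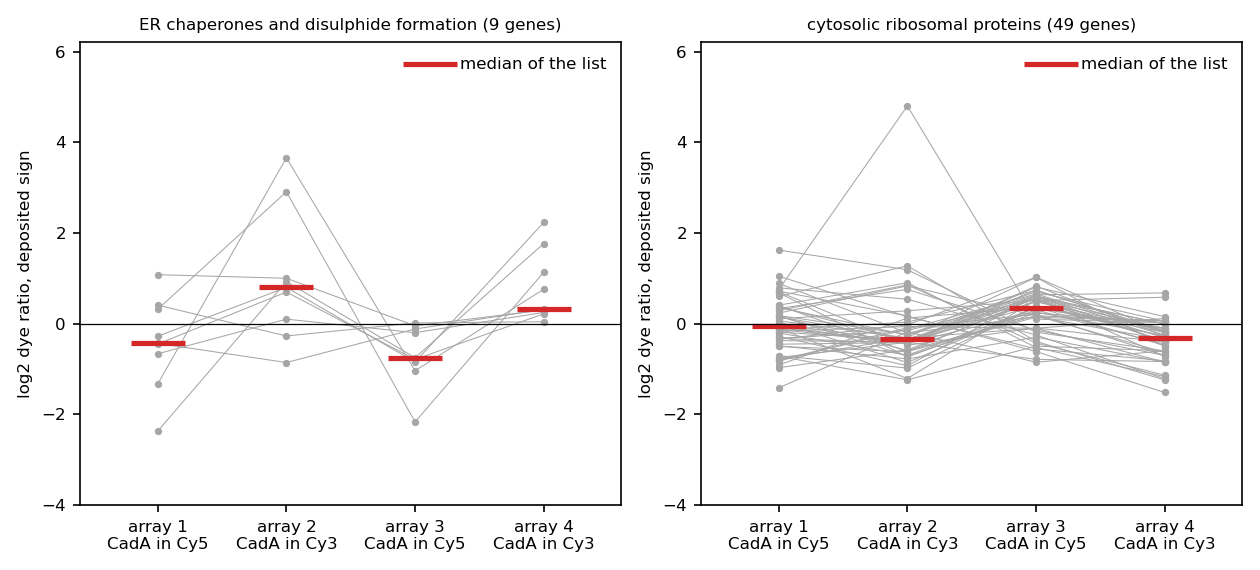
Log2 dye ratio in the deposited sign (vertical axis) on each array (horizontal axis, with the dye that carried CadA RNA) for 9 ER chaperone genes on the left and 49 ribosomal protein genes on the right. Each grey line is a gene and each red bar the list median. The ER medians change sign with the dye orientation on every array. The ribosomal protein medians do so on arrays 2, 3 and 4, while that of array 1 is close to 0.

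Genes for later steps of the secretory route showed smaller shifts to the same side. Of 18 measured genes of ER to Golgi vesicle traffic, 14 had a positive mean (median 0.14), and the list was shifted (camera adjusted p = 0.0053, 0.47 with an estimated correlation). ERV29, a cargo receptor of COPII vesicles, averaged 1.21 ± 0.56 and was positive on all 4 arrays. ERP2, of the p24 family of cargo receptors, averaged 0.84 ± 0.71 on 4 of 4 arrays and SEC31, a coat subunit, 0.92 ± 0.81 on 3 of 4. Their means were 0.53 for ERP2 without array 1 and 0.58 for SEC31 without array 2. Of 26 measured genes of protein glycosylation and GPI anchoring, 18 had a positive mean (median 0.08, camera adjusted p = 0.016, 0.64 with an estimated correlation). PSA1, which makes GDP-mannose, averaged 1.18 ± 1.45 and ALG12, a mannosyltransferase of the ER, 0.69 ± 0.38, each positive on all 4 arrays. GPI8, a subunit of the GPI transamidase, averaged 0.78 ± 2.08 and was positive on 2 arrays. Without array 2 PSA1 averaged 0.48, and GPI8 changed sign to -0.25.

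No gene of these lists passed the threshold, over all features or adjusted over the list alone. Without array 4 both calls were lost (adjusted p = 0.10 for vesicle traffic), and the median of the glycosylation list changed sign to -0.02 (camera adjusted p = 0.66). The glycosylation call was also lost without array 2 (median 0.14, adjusted p = 0.13) and without array 3 (median 0.13, adjusted p = 0.075). Without array 1 its median was 0.22.

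The other lists of the ER gave no call. ER translocation and signal peptidase genes had a median of 0.12 over 13 genes, 10 of them with a positive mean (camera adjusted p = 0.26). That median lies above the 0.08 of the called glycosylation list, so the calls do not separate these lists by size of shift. SEC66 averaged 0.59 ± 0.67, SEC72 0.55 ± 1.90 and SPC2 0.52 ± 0.54. ER-associated degradation had a median of 0.06 over 8 genes (adjusted p = 0.88). In it the ubiquitin ligase gene HRD1 averaged 0.38 ± 0.42, UBC7 0.37 ± 0.85 and YOS9 -0.48 ± 0.77.

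Cell wall integrity genes had a median of 0.30, and 12 of 16 measured members had a positive mean (camera adjusted p = 0.0053, 0.64 with an estimated correlation). The yapsin protease genes YPS3 and YPS1 averaged 0.69 ± 0.48 and 0.62 ± 0.71, positive on 4 and 3 arrays, and YPS1 averaged 0.98 without array 2. GFA1, the first enzyme on the way to chitin, averaged 0.67 ± 0.41 and was positive on all 4. No member passed the threshold over all features or over the list alone. The call was also lost without array 3 (median 0.19, adjusted p = 0.13) and without array 4 (median 0.19, adjusted p = 0.53). The median was 0.46 without array 1 and 0.56 without array 2. The list's median was -0.04 on arrays 1 and 2 and 0.62 on arrays 3 and 4.

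Genes of the translation machinery lay on the opposite side from KAR2. The median of 49 measured cytosolic ribosomal protein genes was -0.21, and 5 had a positive mean (camera adjusted p = 4.8e-05, 0.64 with an estimated correlation). RPS10A averaged -0.54 ± 0.20 and was negative on all 4 arrays, as were 5 other genes of the list. RPL22A averaged -0.51 ± 0.54 and was negative on 3 arrays, with means of -0.65 and -0.36 for its 2 probes and -0.27 without array 2. RPL33B stood apart at 0.99 ± 2.56, with 4.80 on array 2, -0.75 on array 1 and a mean of -0.28 without array 2. The list medians were -0.34, -0.35 and -0.31 on arrays 2, 3 and 4 and 0.06 on array 1. No ribosomal protein gene passed the threshold, over all features or adjusted over the list alone. The call was also lost without array 4 (median -0.17, adjusted p = 0.097).

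Ribosome biogenesis genes had a median of -0.11, and 14 of 49 measured members had a positive mean (camera adjusted p = 0.021, 0.64 with an estimated correlation). RRP1 averaged -0.61 ± 0.42 and was negative on all 4 arrays. The GTPase gene BMS1 went the other way at 0.56 ± 0.69, or 0.31 without array 1. REI1 averaged 0.54 ± 1.73, with 3.09 on array 1 and values below 0 on arrays 2, 3 and 4 (mean -0.32 without array 1), and its 2 probes averaged 0.56 and 0.51. No member passed the threshold over all features or over the list alone. The call was also lost without array 1 (adjusted p = 0.063), without array 3 (median -0.06, 0.31) and without array 4 (0.66). Without array 2 the median was -0.28.

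**Figure D2:**
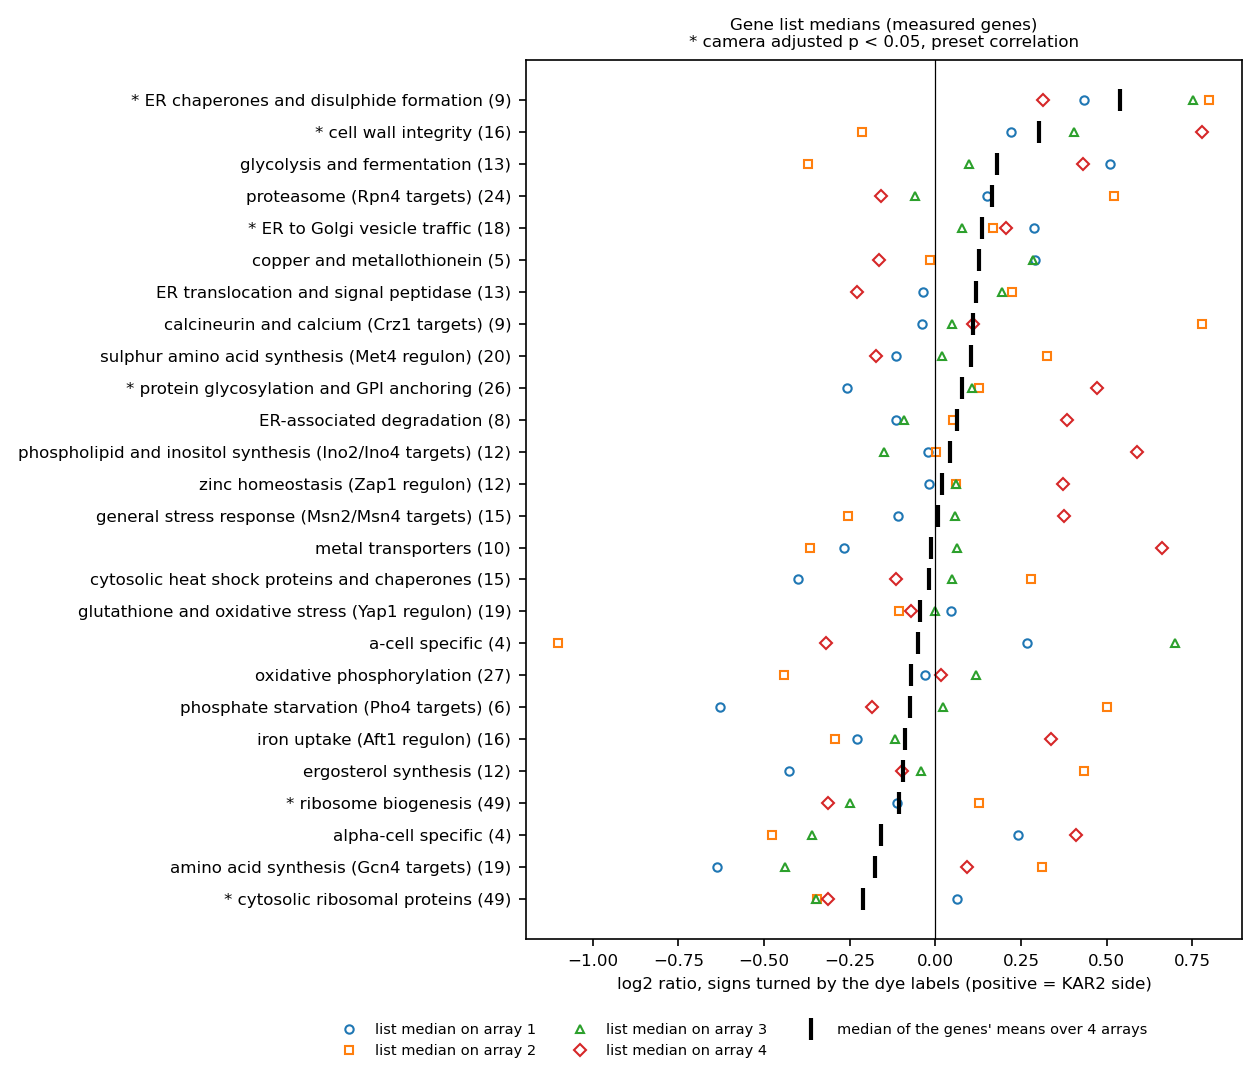
Log2 ratio in turned signs (horizontal axis, positive on the KAR2 side) for the 26 gene lists tested (vertical axis, with the number of measured genes). Open symbols are the list medians on arrays 1 to 4, black bars the median of the genes' means, and stars mark an adjusted p below 0.05 in camera with its preset correlation. ER chaperones (0.54) and ribosomal proteins (-0.21) are at the ends of the range.

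No single gene passed the threshold in the turned signs in the fit of 4 arrays. Over 5946 features, limma called 0 on the positive and 0 on the negative side, and the smallest adjusted p was 0.46. An unadjusted p below 0.05 was reached by 112 features, where 297.3 would be reached by chance. With ordinary statistics per gene in place of limma's shrinkage it was reached by 147, and again 0 passed. The same sign on all 4 arrays was seen for 415 features, against 743.2 by chance.

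The genes with the highest means and a positive sign on every array were MCD4, FPR2, URA1, PAU20 and MPD1. None passed the adjustment over all features in the fit of 4 arrays. MCD4, which adds ethanolamine phosphate to GPI anchors in the ER, was the highest named gene at 2.24 ± 1.17 (4.72-fold, limma adjusted p = 0.82). Without array 1 its mean was 2.73 and its adjusted p 0.022. It also passed when arrays of opposite dye orientation were averaged first, at 0.017 for arrays 1 with 2 and 3 with 4 and at 1.5e-04 for arrays 1 with 4 and 3 with 2. In fits chosen after the data were seen it passed with array weights at 0.027 and on arrays 3 and 4 alone at 8.0e-08. The fits of averaged pairs and of arrays 3 and 4 alone use 2 values per gene. Their p-values therefore lean on the spread of all features more than on that of MCD4. URA1, of pyrimidine synthesis, averaged 1.59 ± 2.02, with 4.57 on array 2 and 1.05 or less on the others, and 0.60 without array 2. PAU20, of the seripauperin family of cell wall mannoproteins, averaged 1.504 ± 0.90.

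The named genes with the lowest means and a negative sign on every array were GTO1, SHM2, TIF3, BTN2 and LYS9. GTO1, a glutathione transferase, averaged -0.91 ± 0.72 and SHM2, the cytosolic serine hydroxymethyltransferase, -0.79 ± 0.25. The translation factor gene TIF3 averaged -0.75 ± 0.38, BTN2 -0.67 ± 0.51 and the lysine synthesis gene LYS9 -0.64 ± 0.42. Each had a limma adjusted p of 1.00. Another 5 features beyond the fifth named gene on the positive side and 6 on the negative side came from probes with no gene name here.

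Most means of named genes depended on single arrays. Leaving out 1 array moved 70 of 89 of them by more than 1.5 times or changed their sign in turned signs, and the sign changed for 21. Among those given here from lists without a call, the sign changed for SEC72, BDS1, FES1, HSP10, CUP9, SER1, RPN11, GAL4, GAL1 and GSH1 without array 2, and ZPS1, GAL3 and STE6 without array 1. In deposited signs the mean moved that far for 62 of 95 named genes.

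Measured genes of the known cadmium defences gave no call as groups. YCF1, MET3 and CUP1-1 had no measured value under their names. The sulphur amino acid list, whose genes feed glutathione synthesis, had a median of 0.10 over 20 genes (camera adjusted p = 0.66). The sulphate transporter gene SUL2 averaged 0.69 ± 1.35, with 2.71 on array 1. STR3 averaged 0.54 ± 0.83, BDS1 0.49 ± 1.29 and MET17 0.43 ± 0.57. The glutathione and oxidative stress list of Yap1 targets had a median of -0.04 over 19 genes (adjusted p = 0.88), which was 0.007 when arrays were scaled to 1 spread and 0.008 with array weights. It included AAD15 at 0.74 ± 1.14, AAD4 at 0.43 ± 0.64 and the superoxide dismutase gene SOD1 at -0.43 ± 0.39. GSH1, which makes the first step of glutathione synthesis, averaged -0.16 ± 0.38, with 2 arrays on each side.

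Lists of metal handling gave no call either. Zap1 targets of zinc homeostasis had a median of 0.02 over 12 genes (camera adjusted p = 0.50). The zinc importer gene ZRT1 was positive on all 4 arrays at 0.51 ± 0.35 without passing the threshold. ZAP1 averaged 0.55 ± 1.00 and ZPS1 -0.57 ± 1.22. Aft1 targets of iron uptake had a median of -0.09 over 16 genes (adjusted p = 0.21), with the biotin transporter gene VHT1 at -0.63 ± 0.90, ENB1 at -0.62 ± 1.05 and COT1 at -0.56 ± 0.50. Of 11 genes in the copper and metallothionein list 5 were measured, and CUP1-1 was not. The 5 had a median of 0.13 (adjusted p = 0.78), with CUP9 at 0.23 ± 0.59, the copper importer gene CTR1 at 0.20 ± 0.18 and CCS1 at -0.20 ± 0.43. After each print block was centred this median was -0.02. Metal transporters had a median of -0.01 over 10 genes (adjusted p = 0.84), which was 0.05 when arrays were scaled to 1 spread, 0.04 after block centring and 0.06 with array weights. PCA1, yeast's own cadmium-exporting P-type ATPase gene, averaged 0.96 ± 1.15 and was positive on 3 arrays.

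Stress lists outside the ER gave no call. The list of cytosolic heat shock proteins and chaperones had a median of -0.02 over 15 genes (camera adjusted p = 0.88) and of 0.01 with array weights. It held SSA3 at 0.39 ± 0.84, FES1 at 0.25 ± 1.35 and HSP10, a mitochondrial chaperone gene, at -0.24 ± 0.92. Targets of Msn2 and Msn4 had a median of 0.01 over 15 genes (adjusted p = 0.75). In that list HSP12, a membrane stress protein gene, averaged 0.79 ± 0.35 and was positive on all 4 arrays, with a limma adjusted p of 1.00 over all features. YGP1 averaged -0.60 ± 0.88 and PNC1 0.43 ± 0.75. Proteasome genes had a median of 0.16 over 24 genes (adjusted p = 0.16), with RPN5 at 0.65 ± 0.97, PRE5 at 0.59 ± 0.72 and RPN11 at 0.40 ± 1.96. Calcineurin targets had a median of 0.11 over 9 genes (adjusted p = 0.21), with CMK2 at 0.87 ± 1.17, MEP1 at 0.45 ± 0.91 and RCN2 at 0.38 ± 0.64.

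Lists of metabolism gave no call in the turned signs. Medians were 0.18 for 13 glycolysis and fermentation genes (camera adjusted p = 0.21), -0.07 for 27 genes of oxidative phosphorylation (0.71), -0.10 for 12 genes of ergosterol synthesis (0.71), 0.04 for 12 Ino2 and Ino4 targets of phospholipid synthesis (0.89), -0.07 for 6 Pho4 targets of phosphate starvation (0.48) and -0.18 for 19 Gcn4 targets of amino acid synthesis (0.13). They included COX5A at 1.11 ± 1.65, SER1 at 0.80 ± 2.43, the acid phosphatase gene PHO5 at -0.68 ± 1.37 and ERG27 at 0.61 ± 0.58. The median of oxidative phosphorylation was 0.10 with array weights. The camera test of the phospholipid list pointed down while its median lay above 0, and the median was -0.003 after block centring. The galactose list had 3 measured genes and was not tested, with GAL4 at 0.25 ± 0.94, GAL3 at -0.24 ± 0.93 and GAL1 at -0.10 ± 0.97.

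Genes that mark the mating type gave no call as groups. The list of genes specific to a-cells, the mating type of W303-1A, had a median of -0.05 over 4 genes (camera adjusted p = 0.67), which was 0.003 when arrays were scaled to 1 spread and 0.15 with array weights. The list specific to alpha-cells had a median of -0.16 over 4 genes (adjusted p = 0.78). AGA2 averaged -0.44 ± 1.14, STE6 -0.08 ± 0.77 and MF(ALPHA)1 0.53 ± 1.10.

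In the signs as deposited, amino acid synthesis genes under Gcn4 stood on the positive side. The median of 19 genes was 0.44, 16 had a positive mean, and the list was shifted (camera adjusted p = 0.0031, 0.93 with an estimated correlation). SER1 averaged 1.62 ± 1.80 and ARO4 1.06 ± 0.71, each positive on all 4 arrays, and HIS7 averaged 1.18 ± 1.58. SER1 averaged 0.73 without array 2 and HIS7 0.53 without array 1, and the list's median was 0.29 without array 3. The ER chaperone list had a median of 0.05 in this reading (adjusted p = 0.68), and 5 of its 9 genes changed sign with the dye orientation on every array. KAR2 read -0.28, 0.80, -0.85 and 2.23 on arrays 1 to 4.

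No gene passed the threshold in this reading either. Limma called 0 features on either side (smallest adjusted p = 0.42), with 695 at an unadjusted p below 0.05 and 568 by ordinary statistics per gene. By chance 297.3 features would reach that unadjusted p. The same sign on all 4 arrays was seen for 1472 features, against 743.2 by chance. Both counts lay above chance in this reading and below it in the turned signs (112 and 415). The named genes with the highest means and the same sign throughout were TRE1 at 1.90 ± 1.67, the amino acid permease gene GAP1 at 1.63 ± 1.42, SER1, NIP100 at 1.58 ± 1.70 and MPH2 at 1.57 ± 1.30. The lowest were RPC34 at -1.45 ± 1.38, PEX22 at -1.35 ± 1.63, the polarity gene SPA2 at -1.32 ± 0.94, YPL077C at -1.24 ± 1.74 and RGD1 at -1.23 ± 0.79. All 10 had a mean farther from 0 on arrays 1 and 2 than on arrays 3 and 4. Without array 2 the mean was 1.09 for TRE1, 1.03 for GAP1, 0.79 for NIP100 and 1.00 for MPH2. Without array 1 it was -0.77 for RPC34, -0.61 for PEX22 and -0.37 for YPL077C.

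The balanced dye swap also let a dye effect be fitted beside the strain effect. No feature had a dye coefficient past the threshold (limma, smallest adjusted p = 0.56), and 490 reached an unadjusted p below 0.05. The estimate of this coefficient is the mean in the deposited signs, which would be the strain estimate if the table was already turned. That mean went with gene length: across 3098 named genes, which are not independent replicates, Spearman's rho was 0.32, against 0.11 for the turned mean. The 620 shortest genes had a deposited median of -0.26 and the 620 longest a median of 0.13. In the turned signs these medians were -0.05 and 0.04.

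**Figure D3:**
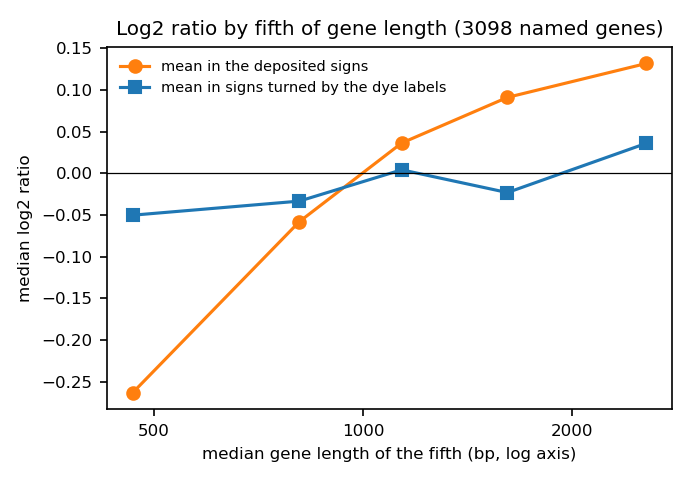
Median log2 ratio (vertical axis) of 5 classes of about 620 named genes ordered by gene length (horizontal log axis, median length in bp). The median in the deposited signs (circles) goes from -0.26 for the shortest class to 0.13 for the longest. That in the turned signs (squares) stays between -0.05 and 0.04.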

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

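A value on 1 array lay far from those on the other 3 for 1 of 26 lists and 6 of 89 named genes in turned signs. The measure is the gap to the nearest other array over the whole range, and chance passes it for about 1 in 20 groups. The tests by block centring, by pairs of arrays and of the count of genes over sign patterns were chosen after values that bear on them had been seen. The tests by gene length were added after the data were examined, and what they and the count of lists should show was written down before their own results were seen.

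The median of the cytosolic ribosomal protein list was 0.06 on array 1 and between -0.31 and -0.35 on the others, a gap of 0.914 of the range. SUL2 stood at 2.71 on array 1 (0.933), HSP12 at 1.31 on array 1 (0.875) and REI1 at 3.09 on array 1 (0.836). On array 2, PNC1 stood at 1.54 (0.836), YPS1 at -0.44 (0.882) and RPL33B at 4.80 (0.862). All 7 lay farthest out on array 1 or 2, the arrays with the wider spread.

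The ER chaperone list lay on the positive side on each array. A position effect on the slide is argued against, since the list's median was 0.562 after each print block was centred. Gene length is argued against as well, with a median of 0.554 after the length trend was removed. The shift did not rest on 1 pair of arrays: the lower of the pair medians was 0.503. A difference between the strains, which the design names, stays open and may be the source, with its direction unsettled. If the table was already turned to 1 strain direction, a dye effect stays open in its place. Cells and RNA handled differently before labelling were not tested.

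The ribosomal protein list lay on the negative side. Its median was -0.174 after the length trend was removed and -0.196 after block centring, so neither alone accounts for it. Whether it rests on a single pair of arrays cannot be told apart from a shift in both, since the median nearer 0 was -0.136, on arrays 1 and 2. The strain difference or, in a table already turned, a dye effect may contribute here too, and both stay open.

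With 4 arrays there are 8 patterns of signs, too few for a share under 0.05. In turned signs 0 genes passed the threshold, as in all 8 patterns, where the highest other count was 0. The turned signs shifted 6 lists. Counting this pattern itself, 2 patterns gave as many or more, and the only other one gave 9. That other pattern turns arrays 2 and 3 against arrays 1 and 4.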

How the results depend on the processing

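Array weights, arrays 1 and 2 or 3 and 4 alone, block centring and removal of the length trend were chosen after the data were seen. Fits of averaged pairs or of 2 arrays use 2 values per gene, so their p-values lean on the spread of all features. In turned signs, 0 genes passed on either side at the main setting, and most alternatives gave 0 again. With arrays 1 with 2 and 3 with 4 averaged first, 2 passed on the positive side, MCD4 and a probe without a name. With 1 with 4 and 3 with 2 averaged, 4 passed, MCD4, FPR2 and 2 unnamed probes. Array weights gave 4, MCD4 and 3 unnamed probes. Arrays 3 and 4 alone gave 9 on the positive side, MCD4, LHS1, KAR2 and 6 unnamed probes, and 1 unnamed probe on the negative side. Fits without 1 array gave 0 to 1, the 1 being MCD4 without array 1. In deposited signs, 5 positive and 2 negative features passed with arrays 1 with 2 and 3 with 4 averaged, and 114 and 91 on arrays 1 and 2 alone, which correlated at r = 0.35. The cause was not tested.

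In turned signs, 4 lists were shifted to the positive and 2 to the negative side. Camera with an estimated correlation and fry each gave 0 and 0, and the ER chaperone list (median 0.54) was lost under both (adjusted p = 0.31 and 0.10). Arrays with CadA in Cy5 alone gave 0 and 1, without the ER list (median 0.56), and those with CadA in Cy3 alone 2 and 1. Averaging arrays 1 with 4 and 3 with 2, and a threshold of 0.01, each left 1 on the negative side. Arrays 1 and 2 alone gave 1 and 0, and arrays 3 and 4 alone 6 and 3. Turning every sign gave 2 and 4 by construction. Fits without 1 array gave 1 to 4 positive and 0 to 4 negative lists. The ER list had a positive median in all 28 alternatives, between 0.46 and 0.65, and stayed called in 25. Its adjusted p ranged from 3.9e-11 to 0.31. The ribosomal protein list stayed negative in all 28 and was called in 23. Many of the 28, such as the dye term, pair averaging, shrinkage and thresholds, cannot move either median. Shrinkage, the minimum of arrays and the 1.5-fold minimum left the camera result as it was (adjusted p = 3.7e-06 for the ER list in each). They add no support to the counts of calls. The signs as deposited are not among the 28. In that reading the medians were 0.05 for the ER list (camera adjusted p = 0.68) and -0.07 for ribosomal proteins (0.54).

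The glycosylation list turned to -0.023 on arrays with CadA in Cy5 alone and to -0.058 on arrays 1 and 2 alone, and ran from -0.024 to 0.22 over fits without 1 array. On arrays 1 and 2 alone the cell wall list turned to -0.044 and ribosome biogenesis to 0.072. In deposited signs 1 list was shifted, to the positive side. The number was 0 with an estimated correlation and on arrays 3 and 4 alone. Fry gave 0 on the positive and 1 on the negative side, the Yap1 list (median -0.10, fry adjusted p = 0.011). CadA in Cy3 alone gave 2 and 1, turning every sign 0 and 1, and fits without 1 array 1 to 2 positive lists. The causes were not tested. Both minimums of arrays changed nothing, since no probe had values on only some arrays. Signal over background was not analysed here.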

Other observations

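Seripauperin (PAU) genes, a family of small cell wall mannoproteins whose members mostly lie near chromosome ends, mostly had positive means in turned signs. The family was chosen after its values were seen, so no p value for it as a group is given. Whether the probes of the family tell its members apart was not tested, so the 9 may not count as separate genes. Of 9 measured members, 8 had a positive mean and the median was 0.49. It was 0.31 without array 1, and in deposited signs it was -0.21. PAU20 averaged 1.504 ± 0.90 (SD, n = 4), PAU5 0.83 ± 1.20 and PAU17 0.75 ± 0.53, while PAU12 was at -0.01 ± 0.90. The family's array medians were 1.19, 0.29, 0.60 and 0.46, and did not follow those of the ER chaperone list at 0.43, 0.80, 0.75 and 0.31. No member passed limma's adjustment over all features (adjusted p = 1.00 for each).

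All pairs of arrays but 1 correlated above 0 in the deposited signs, although the dyes were swapped. The tests of this pattern were chosen after it was seen. In the mean of the deposited signs, 2 probes of 1 gene correlated at -0.0416. That mean goes with gene length, which such probes share, so the check can miss a property of genes. It does not decide whether the table was already turned to 1 strain direction. Slide position alone is argued against for the pairs on average, since the mean of the 6 correlations was 0.232 after block centring. For arrays 3 and 4 the correlation went from 0.23 to -0.011, so this does not cover that pair. A length-dependent dye ratio is a candidate source: rho with gene length was at least 0.134 on every array. It need not be the whole of it. The Gcn4 list was called by the preset correlation over all 4 arrays in this reading only (adjusted p = 0.93 with an estimated correlation). Its call held after the length trend was removed, with a median of 0.40 and a camera adjusted p of 0.041, against 0.44 and 0.0031 before.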
